A study of Pimephales promelas with 16 samples.

How the data were processed

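Total RNA of 16 livers of male fathead minnows, 8 control and 8 exposed to EE2 at 25 ng/L for 96 h, was labelled with Cy3 and hybridised to 1 Agilent array each, per the labels' protocols. The arrays were scanned and quantified with Agilent Feature Extraction 10.1.1.1, per the file headers. Samples were assigned to groups from the treatment given in the labels and are named by the number in their titles. The 2 groups share no replicate number, so the samples were not paired. The design text calls the replicates biological, and nothing else about the animals or tanks was used.

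The intensity values deposited for each spot include the mean signal, the median local background and a processed signal that Feature Extraction had background-subtracted and detrended within the array, per the file headers. Signals too close to background had been replaced by a surrogate value, per the file headers, on between 15.8% and 30% of the spots of an array. Nothing had been scaled between arrays. The deposited files also hold flags for spots well above background, saturated spots and outlier spots, per the file headers. A table of log2 values of the authors was deposited as well, covering 45911 spots. Set against the scanner files, 100% of its values for spots with neither a surrogate nor an outlier flag lay within 0.05 of log2 of the processed signal. Surrogate and outlier spots made up 9.06% of its values, and 97.1% of those that could be compared equalled, within 0.001, the lowest other value of the same spot within the treatment group. The medians of its columns were 6.18, 6.14, 6.12, 6.28, 6.14, 5.68, 5.80 and 5.44 for control replicates 1, 2, 3, 7, 8, 9, 13 and 14, and 5.37, 5.87, 5.74, 6.04, 5.83, 5.61, 5.75 and 5.51 for EE2 replicates 5, 6, 10, 11, 12, 16, 17 and 18, so the arrays had not been brought to a common scale, and the step that chose its spots is not given in the sources used here. It served only as an alternative.

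The processed signal was set to at least 1, taken to log2, and reduced by its 75th percentile over the non-control spots of the array. Control spots and spots flagged as non-uniform or population outliers were left out, and the spots of a probe name were averaged. A probe counted as well above background on an array when at least 50% of its spots did, and was tested when this held on at least 6 arrays of control or of EE2. The groups were compared with limma 3.58.1 in R 4.3.3, by a linear model with group as the only term and empirical Bayes moderation with a trend on brightness. Probes with a Benjamini-Hochberg adjusted p under 0.05 were called, and all tests were two-sided. Single values per array were compared by an exact permutation test of the difference of group means over all assignments of the 16 arrays. A probe not well above background on any array of a group has only an approximate bound there. For it, the mean of the bright group was set against the mean, over the dim group's arrays, of the higher of the probe's own level and the lowest level of a spot well above background on that array.

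Probe names were looked up in the RefSeq gene table for the species (assembly fPimPro1.hap1.1) and 0 matched. The description of every probe read "Unknown". Gene-level counts and tests of gene lists, which had been planned before the data were examined, were therefore not run. By the rule fixed before the data were examined for this case, the 2 probes with the largest rise and the 2 with the largest fall are named by their identifier and sequence.

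The slide was tested as a batch because each slide held both groups; the arrays of a slide were also scanned together, so slide and scan cannot be separated. It was fitted as a fixed term, as a random block and with an interaction with group, and each slide was fitted alone. Other alternatives changed the background correction (normexp with an offset of 50), the scaling (quantile, median and cyclic loess), the filter on dim probes, the moderation, the weights of arrays, the treatment of outlier spots, the threshold (adjusted p under 0.01, or a change of at least 1.5-fold in addition), the source of values, and left out each array in turn with the same probes tested.

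The model was tested on simulated arrays before use. Values for 25362 probes with complete data were drawn from the control means and the spread of each probe, with 200 probes changed. For EE2 against control with 8 arrays each, 94% of the probes changed 8-fold and 86% of those changed 4-fold were called in the right direction. The shares were 56% of those changed 2-fold and 8% of those changed 1.5-fold. These were 47, 43, 28 and 4 right calls of 50 each, beside 12 false calls. The probes were drawn independently of each other and without a slide effect, unlike real arrays. Because so few probes were changed, the adjusted threshold was stricter there than in the real comparison, so the shares of right calls do not carry over to it. The number of arrays limits the precision. The variation between spots printed 10 times on an array had a median SD between 0.09 and 0.14 on the log2 scale, except on control replicate 9, where it was 0.28 and the scanner software's own check of replicate spots was out of range.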

Results

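Liver RNA of male fathead minnows (*Pimephales promelas*), a small freshwater fish widely used in toxicity testing, was measured on 16 one-colour microarrays. The fish of 1 group had been exposed to 17α-ethinylestradiol (EE2), a synthetic estrogen used in oral contraceptives, at 25 ng/L for 96 h, and the other group served as control. Each group held 8 biological replicates according to the design. The title of the series places it as the data of 1 laboratory in a comparison of microarrays between laboratories, and the comparison within it asks which liver transcripts differ between exposed and control males. The arrays lay on 2 slides of 8, with 6 control and 2 EE2 arrays on slide 1 and 2 control and 6 EE2 arrays on slide 2. Each array carried 61053 spots of 60-base probes other than controls, under 49849 probe names and 44586 distinct sequences. The names are identifiers of the array's design, and the files do not pair them with genes, so levels are reported by probe.

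The brightness of the arrays overlapped between the groups. The 75th percentile of the log2 signal was 7.96 ± 0.26 (SD, n = 8) on control arrays and 7.73 ± 0.19 (SD, n = 8) on EE2 arrays, a difference of -0.23 (exact permutation test, two-sided, p = 0.072; adjusted p = 0.144 over 8 array measures). The difference was -0.47 on slide 1 and 0.06 on slide 2. Leaving out control replicate 9, control replicate 14 or EE2 replicate 11 brought the exact p to 0.027, 0.0267 and 0.035. Between 22680 and 30780 probes lay well above background on a control array and between 22730 and 27326 on an EE2 array, and the difference of -1968 probes did not pass the exact permutation test (p = 0.134; 0.0336 without control replicate 9). It was -3826 probes on slide 1 and 1219 on slide 2, in opposite directions. No spot was saturated, and no pair of arrays held identical values. A probe was tested when it lay well above background on at least 6 arrays of a group, which 25665 probes, or 51.5% of the names, did.

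EE2 exposure was accompanied by both rises and falls across the liver transcripts. Of the probes tested, 3153 were higher and 3877 lower in EE2 livers (limma, Benjamini-Hochberg adjusted p under 0.05), together 27.4% of those tested. They stood for 2793 and 3531 distinct sequences, and no sequence was called in both directions under different names. The median change was 2.08-fold among probes that rose and 1.92-fold among probes that fell. The rises reached further than the falls: 1680 probes rose and 1731 fell by at least 2-fold, 550 rose and 322 fell by at least 4-fold, and 215 rose and 78 fell by at least 8-fold. A change of at least 100-fold was found for 29 probes that rose and for 0 that fell. Sizes that large rest in part on levels near background. For a check, every level not well above background was raised to the lowest level well above it on the array. Then 158 rose and 58 fell at least 8-fold, and 25 rose at least 100-fold. With normexp background correction 89 rose and 29 fell at least 8-fold, but its offset of 50, added to every signal, itself makes changes smaller. The split between rises and falls depended on the scaling: with arrays scaled to their medians, 3660 probes were higher and 2937 lower.

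The levels of 830 probes that rose and 645 that fell did not overlap between the 8 arrays of each group, where a probe without any difference does so in 0.0155% of the assignments of arrays to groups. Of the probes that rose, 2213 were well above background on all 16 arrays, and of those that fell, 2802. On the 2 slides fitted apart, 429 probes were called on slide 1 and 4069 on slide 2. Of the slide 1 calls, 415 (96.7%) had the same sign on slide 2, whose arrays are independent of them. Of the slide 2 calls, 3781 (92.9%) had the same sign on slide 1. In limma with an interaction of slide and group, the EE2 change differed between slides for 3 probes. An unadjusted p under 0.05 for it was found for 1888, against 1283 by chance. On both slides 351 probes were called in the same direction, against 35 same-direction calls for independent lists of these sizes. None was called on both in opposite directions. With slide as a block, 2580 probes were higher and 2923 lower, of which 2306 and 2597 were among those called without it, and 0 were called in opposite directions by the 2 fits. The slide itself was called for 0 probes in limma with group in the model, while 3625 probes had an unadjusted p under 0.05 for it, against 1283 by chance; with other scalings it was called for up to 81 probes.

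**Figure D1:**
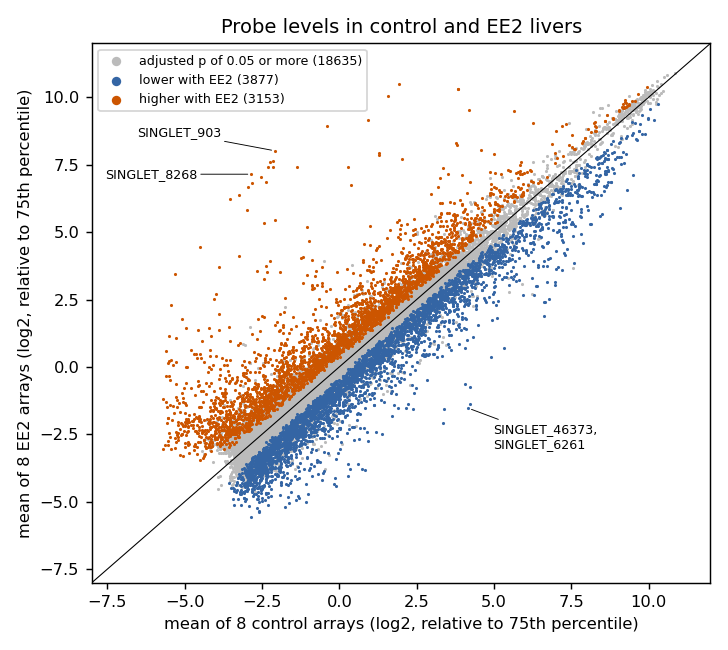
Mean log2 signal of each tested probe on 8 control arrays (horizontal) and 8 EE2 arrays (vertical), relative to each array's 75th percentile, with the line of equal levels. Orange points are the 3153 probes higher with EE2, blue points the 3877 lower and grey points the rest; the probes with the largest changes are labelled.

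The largest rise was that of probe SINGLET_903 (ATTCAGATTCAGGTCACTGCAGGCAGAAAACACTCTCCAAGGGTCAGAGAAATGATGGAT). Its level relative to the array's 75th percentile was -2.08 ± 2.51 (SD, n = 8) in control and 8.01 ± 0.25 (SD, n = 8) in EE2 livers on the log2 scale, a log2 change of 10.09 ± 0.81 (SE; limma, adjusted p = 1.26e-07). Probe SINGLET_8268 (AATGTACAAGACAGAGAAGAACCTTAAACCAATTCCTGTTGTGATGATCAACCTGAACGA) followed, with -2.84 ± 2.15 (SD, n = 8) in control and 7.15 ± 0.51 (SD, n = 8) in EE2 livers, a log2 change of 9.99 ± 0.71 (SE; limma, adjusted p = 2.67e-08). Both were well above background on 8 of 8 EE2 arrays and on 5 of 8 control arrays, so the control means rest in part on levels not well above it. With those levels raised to the lowest level well above background, SINGLET_903 was 790-fold and SINGLET_8268 705-fold higher with EE2. These are estimates on this signal and not lower bounds. With normexp background correction, whose offset itself makes changes smaller, the log2 changes were 8.46 and 8.24. With slide as a block the changes were 9.63 and 9.61, and within the slides they were 10.77 and 8.49 for SINGLET_903 and 11.16 and 8.06 for SINGLET_8268. Among males, induction of the egg-yolk precursor vitellogenin in the liver is the textbook response of fish to an estrogen, but which probes stand for it cannot be read from the names used here.

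The 2 largest falls belonged to the probes SINGLET_46373 and SINGLET_6261, which carry the same sequence (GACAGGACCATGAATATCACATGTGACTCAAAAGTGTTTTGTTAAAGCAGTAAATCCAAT) and so measure the same target. SINGLET_46373 stood at 4.16 ± 1.99 (SD, n = 8) in control and -1.53 ± 2.23 (SD, n = 8) in EE2 livers, a log2 change of -5.69 ± 0.96 (SE; limma, adjusted p = 0.000361). SINGLET_6261 changed by -5.61 ± 0.93 (SE; limma, adjusted p = 0.000311). Both were well above background on all 8 control arrays, and on 6 and 5 of the 8 EE2 arrays. The changes were -6.26 and -6.16 with slide as a block, and -4.49 and -4.55 with normexp background correction. With levels not well above background raised as above, the probes were 42.4-fold and 44.4-fold lower with EE2, which are estimates and not lower bounds. On slide 1 alone, with 2 EE2 arrays, they were -6.20 and -6.10 and no longer passed (limma, adjusted p = 0.0982 and 0.1). For SINGLET_46373 the groups overlapped through control replicate 3 alone, at 0.11: the other 7 control livers lay between 3.16 and 6.47, all above the highest EE2 level of 1.89.

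**Figure D2:**
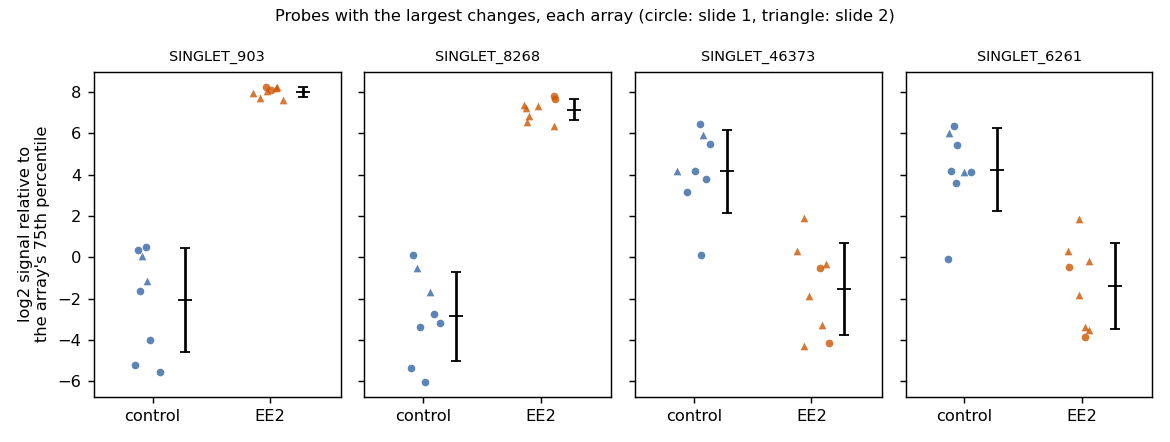
Log2 signal relative to the array's 75th percentile (vertical) for the 4 probes with the largest changes, with each of the 16 arrays as a point, circles for slide 1 and triangles for slide 2; bars give the mean and SD of 8 arrays. SINGLET_903 and SINGLET_8268 are higher on every EE2 array than on any control array, while for SINGLET_46373 and SINGLET_6261, which share a sequence, 1 control array lies within the range of the EE2 arrays.

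Some transcripts were detected in 1 group only. Of the probes that rose, 103 were not well above background on any control array, and 51 of these were well above it on all 8 EE2 arrays. Their change is known only as an approximate bound. It was taken against the higher of the dim probe's own signal and the lowest spot signal well above background on each control array. On this signal the bounds had a median of 5.04-fold and reached 127.7-fold. The lowest spot signal well above background is not each probe's own detection limit, so they are not strict lower bounds. Of the probes that fell, 139 were not well above background on any EE2 array. Among them, 18 were well above it on all 8 control arrays. By this approximate bound 11 of the 18 were at least 2-fold lower with EE2, up to 4.77-fold, and 1 gave no bound.

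The 29 probes that rose at least 100-fold took up a visible part of the signal of the exposed livers. They held 2.87% ± 0.35 (SD, n = 8) of the summed signal on EE2 arrays and 0.0411% ± 0.0383 (SD, n = 8) on control arrays, a difference of 2.83 percentage points (exact permutation test, two-sided, p = 0.000155, the smallest the 8 against 8 arrays can give; adjusted p = 0.000414 over 8 measures). The difference was 3.19 points on slide 1 and 2.71 on slide 2. Their levels varied more among control than among EE2 livers: the median SD over these probes was 1.91 in control and 0.36 in EE2 livers on the log2 scale, and 28 of the 29 varied more in control livers. With levels not well above background raised as above, the median SD in control livers was 1.36. On control replicate 3, 2 of the 29 probes, which share a sequence, stood at 8.28 and 8.23, above their level on every EE2 array (at most 6.36). Without them the share was 0.0275% ± 0.0286 (SD, n = 8) on control and 2.85% ± 0.35 (SD, n = 8) on EE2 arrays, and the median SDs were 1.82 and 0.34. Over all tested probes the median SDs were 0.48 and 0.44. The probes were selected on the same arrays, so their share is not independent of the test that called them.

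**Figure D3:**
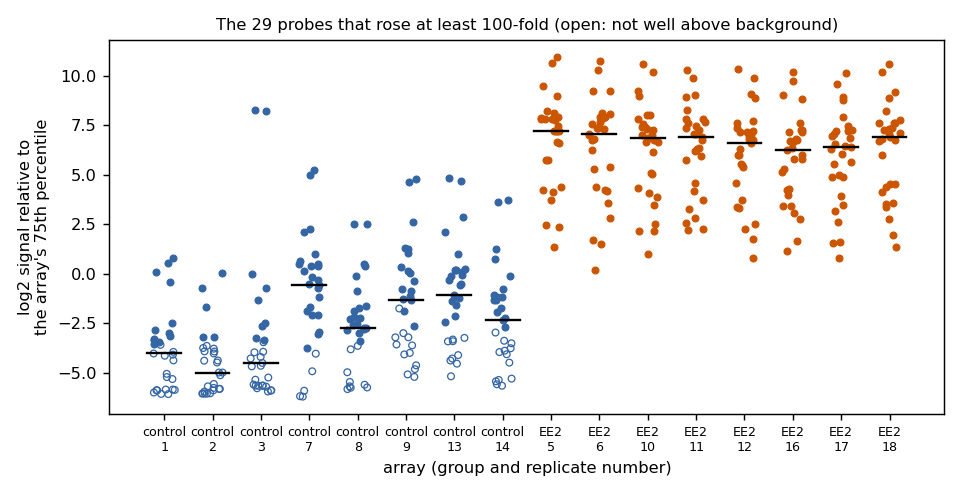
Log2 signal relative to the array's 75th percentile (vertical) of the 29 probes that rose at least 100-fold, on each of the 8 control and 8 EE2 arrays (horizontal); open points were not well above background and black lines are medians over the probes. Control replicates 1, 2 and 3 had 12, 5 and 9 of the 29 probes well above background, and the other control arrays between 16 and 24.

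Every exposed liver stood apart from the control livers. For each array in turn, the probes that changed at least 4-fold were chosen on the other 15 arrays, and their mean level was read on the array left out. The mean of the rising probes was 1.08 ± 0.32 (SD, n = 8) on EE2 arrays and -1.93 ± 0.23 (SD, n = 8) on control arrays, with ranges of 0.38 to 1.37 and -2.24 to -1.67. The mean of the falling probes was -0.31 ± 0.45 (SD, n = 8) on EE2 arrays and 1.84 ± 0.33 (SD, n = 8) on control arrays. The permutation test of the group means gave p = 0.000155 for each score (adjusted p = 0.000414). The probes were chosen with the true groups of the other arrays and were not chosen anew for each assignment. The scores also share most of the arrays used for choosing, so these p-values are not exact and decide nothing here. Within the slides the differences were 2.74 and 3.17 for the rising probes and -1.77 and -2.18 for the falling probes. EE2 replicate 5 had the lowest rise score and the highest fall score of its group, and still lay outside the range of the control arrays for both.

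**Figure D4:**
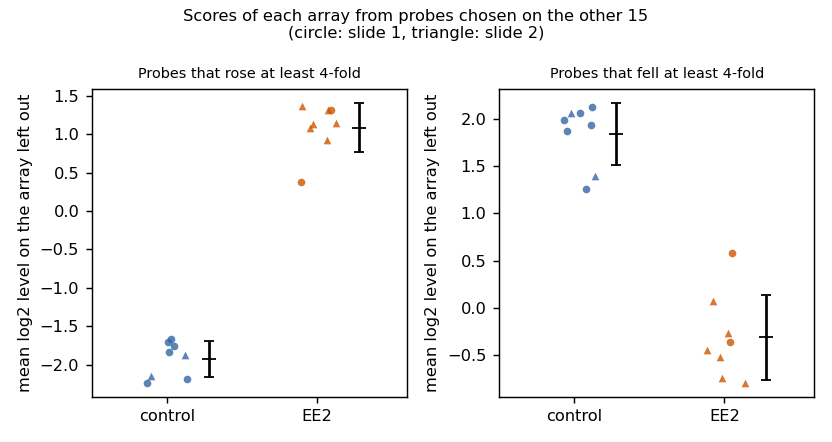
Mean log2 level (vertical) of probes that rose (left) or fell (right) at least 4-fold, chosen without the array shown, with each array as a point, circles for slide 1 and triangles for slide 2; bars give the mean and SD of 8 arrays. The EE2 arrays lie between 0.38 and 1.37 for rising probes, all above the control arrays, and between -0.79 and 0.58 for falling probes, all below them.

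Sequences printed under several names show the noise between spots on the same arrays, which leaves out the spread between livers. For 2890 tested sequences with at least 2 names, the change measured under the first and the second name differed by a median of 0.08 on the log2 scale (SD of the difference 0.22), while the median SE of a change between the groups, which includes the spread between livers, was 0.24. The log2 changes measured on slide 1 and on slide 2 correlated with r = 0.67 across probes, which are not independent replicates.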

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

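The tests of the strongly induced probes among control livers were chosen after the result was seen; the test on other splits of the arrays was chosen before its result was seen. The requirement that the interval of the share of low pairs lie above its limit before mixing is excluded was added after that share was seen. Over 15 measures in 2 groups, 6 values stood further from the rest of their group than Dixon's 95% critical value allows, where chance flags about 1 in 20 groups; the measures are not independent.

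Of the 6 values, 3 concern control replicate 9. Its replicate spots had a CV of 32%, against 9.38% to 14.3% on the other control arrays, the median SD over 10 printings was 0.28, against 0.09 to 0.11, and its median correlation with the other control arrays was 0.898, against 0.926 to 0.94. On EE2 replicate 16 the SD over 10 printings was 0.14, against 0.10 to 0.12 on the other EE2 arrays. The rise score of EE2 replicate 5 was 0.38, against 0.92 to 1.37 for the other EE2 arrays; it was also the dimmest array by its 75th percentile. The level of SINGLET_6261 on control replicate 3 was -0.057, against 3.59 to 6.37 on the other control arrays, and SINGLET_46373, which has the same sequence, stood at 0.11 there. Without control replicate 9 and EE2 replicate 5 together, an alternative added after seeing the data, 3463 probes were higher and 3966 lower.

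Chance is an unlikely source of the calls between the groups: 1 of 100 splits of the 16 arrays into 8 and 8, the real one, called as many as 7030 probes. Not all possible splits were run, and 1 of 100 is the smallest share that these can give. The splits take the fish as independent units. No tank was known for the samples here, so a tank difference that went with the groups would pass this test as well. The highest of the other splits, with 396, was the split by slide, which keeps 6 of the 8 EE2 arrays together; with slide as a block 2580 probes were higher and 2923 lower.

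The probes that rose at least 100-fold differed widely among control livers. Their median level as a share of the EE2 mean was 0.765% on control replicate 7, 0.525% on replicate 13, 0.509% on replicate 9, 0.239% on replicate 14 and 0.174% on replicate 8, while on replicates 1, 2 and 3 most of them were not well above background, although 2 of the 29, which share a sequence, stood on replicate 3 above every EE2 array. The slide was not the whole cause, because the mean over these probes ranged over 3.48 log2 units among the control arrays of slide 1 and differed by 1.13 between the slides. A small amount of EE2 liver RNA mixed into control samples would put all of these probes at about one share on an array: of 109 pairs of probe and control array bright enough to judge, on the 5 arrays where most of the probes were well above background, 90 lay within 1.5 log2 units of the array's median share, 12 above and 7 (6.42%, exact 95% interval 2.62% to 12.8%) below it, where at most 5% had been set as the limit. Mixing and a graded estrogen response of these control livers cannot be told apart, since the interval holds that limit. The interval also takes the pairs as independent, although the same probes recur on the 5 arrays, so it may be too narrow. The dimmer of these probes, of which 6 of 39 pairs lay that far below their own median share, are nearest to background. A difference between control animals was not tested, and the arrays of replicates 1, 2 and 3 take the first 3 places of slide 1, but the order in which samples were handled is not given in the sources used here.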

How the results depend on the processing

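Some tests here were added after seeing the data: 1 name per sequence, leaving out 2 arrays together, centring on the tested probes, rescaling the authors' table and raising dim levels. No refitted alternative called a probe in the direction opposite to the main calls; with dim levels raised, which was not refitted, the change of 2 called probes turned sign. The count of higher probes stayed within 1.5 times of 3153 in 19 of 22 alternatives (2177 to 3796) and that of lower probes within 1.5 times of 3877 in 19 of 22 (2921 to 5654). Leaving out 1 array gave 2734 to 3348 higher and 3297 to 4026 lower. With 6 control and 2 EE2 arrays, slide 1 alone called 300 higher and 129 lower, and with 2 control and 6 EE2 arrays, slide 2 alone called 2177 higher and 1892 lower; the cause was not tested. At an adjusted p under 0.01, 1893 were higher and 2028 lower. The authors' table, whose arrays are not on a common scale, gave 1538 higher and 5654 lower and moved the median change of all tested probes by -0.23 on the log2 scale; rescaled to the 75th percentile it gave 2905 and 4098.

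The slide was called for 0 probes, but for 15 with quantile normalization, 81 with median scaling, 27 with cyclic loess, 7 among probes well above background on all 16 arrays, 22 without the trend, and 27 with the authors' table rescaled. Leaving out 1 array gave 0 to 5, with 5 without control replicate 2, 2 without EE2 replicate 11 or 12, and 1 without control replicate 9; the cause was not tested.

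The surplus of falls, 55.1% of the calls, did not hold under every setting: the share was 30.1% on slide 1 alone and 46.5% on slide 2 alone. With all 16 arrays it was 44.5% with median scaling, 47.2% with cyclic loess and 48.7% with normexp background correction. Median scaling, cyclic loess and normexp moved the median change of all tested probes from -0.07 to 0.01, -0.01 and -0.003 on the log2 scale. Centring each array on the median of the tested probes left the median change at -0.08 and the share at 55.4%, so this step decided nothing. Signal taken up by the strongest risers would give a shift common to all probes. Reducing each array by its 75th percentile had already taken out a shift exactly common to all. A shift that differs between probes was not tested, and the cause of the surplus stays open. Dimness was not the whole cause of the surplus found with the 75th percentile, since the share was 54% among calls above the median brightness and 56.8% below it. Counts at 8-fold or more depend on signal near background: with normexp 89 rose and 29 fell that far, against 215 and 78. Among probes well above background on all 16 arrays the counts were 56 and 36, a filter that by its construction removes probes that rose from or fell to a level near background. The changes of SINGLET_46373 and SINGLET_6261 missed the threshold only on slide 1 alone; the 4 named probes were not tested among probes well above background on all 16 arrays. The mean of all probes of a gene, camera and fry were not run, because no probe had a gene name.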

Other observations

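The tests of this part were chosen after the patterns were seen. A set of 77 probes with 69 distinct sequences was on in some livers and off in others of both groups: their 16 levels fell into 2 sets separated by a gap of at least 3 log2 units, with at least 1 array of each group in each set and at least 3 arrays in each. The median gap was 4.71 log2 units, or 26.2-fold, and of the arrays in the lower set, 55.4% on average were not well above background. The widest gap, 7.07, was that of CONTIG5921 (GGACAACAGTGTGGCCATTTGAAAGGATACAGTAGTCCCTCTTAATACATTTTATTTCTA), chosen after its values were seen, which was in the upper set on 4 control and 4 EE2 arrays, with levels of 6.89 to 8.44 there and -5.92 to -0.19 on the other arrays. By the selection itself these probes do not separate the groups, and 2 of the 69 were called between EE2 and control.

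Spot artefacts were not the whole cause of these states: another printing of the same sequence under another name showed exactly the same states in 17 of 20 comparisons (85%). Where both names of a sequence were in the set, the pair was compared from each name, so the 20 comparisons stand for fewer pairs. Both names of such a pair had been chosen for their gap on these same arrays. RNA of 1 other tissue or animal in some samples would turn the probes on together. The commonest pattern over the 16 arrays, counted together with its reverse, was shared by only 6 of the 69 sequences (8.7%), and there were 46 patterns. Of these, 13 were shared by 2 or more sequences and held 36 of the 69. The count asks for the same state on all 16 arrays and speaks only to a single source. The slide was not the whole cause for those that could be tested, since of the 47 sequences in the upper set on 5 to 11 arrays, the only ones for which the test can pass, 1 (2.13%) split by slide at an unadjusted Fisher exact p under 0.05. Some of the sequences overlap, so they are not all separate transcripts. Inherited differences between the fish, either in whether a transcript is made or in the sequence under a probe, may give such states, and the arrays cannot tell these apart; no biological explanation was tested, because the labels give no group for it.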
